A study of Escherichia coli and Homo sapiens with 9 samples.

How the data were processed

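The series measured N6-methyladenine (6mA) at single adenines in 9 sequencing libraries of 3 groups. The groups were Escherichia coli K12, E. coli SCS110, and mitochondrial DNA of HepG2, a human liver cancer cell line, with 3 libraries each. Per the labels' protocols, DNA was sheared to fragments of 200 to 500 bp, adapters were ligated, and 10 ng of heat-denatured DNA was treated with 2.8 µM of the adenine deaminase ABE8e for 4 h at 37 °C before PCR. ABE8e turns unmodified adenine into inosine, which is sequenced as G, while 6mA resists the enzyme and is sequenced as A. A base read as G is called converted here and a base read as A unconverted. The share of unconverted bases therefore holds 6mA together with adenines that the enzyme missed.

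The deposited values are counts, per the file headers: for each listed adenine position and strand, whole numbers of converted and of unconverted bases, with a quality letter for every base. They were not normalised. Per the submitters' processing notes, FastQC 0.11.8, Trim Galore 0.6.7 and cutadapt 3.5 were used, with the builds ASM584v2 for E. coli and GRCh38.p13 for human DNA. The aligner, the program that counted the bases, and any removal of duplicate reads were not given in the sources used here. No genome sequence was used. The positions listed on the plus strand were taken as A, those listed on the minus strand as T, and every other position as S, meaning C or G. No position was listed on both strands of the E. coli chromosome. A gene table of ASM584v2, with gene starts and ends and no strands, gave the gene names. Of its 4290 protein-coding genes, 90.2% had a start-codon pattern at an annotated end without any shift of the coordinates, against 6.67% and 5.52% with a shift of 1 bp in either direction. All coordinates are 1-based. For mitochondrial DNA no annotation was used, and bins of 1000 bp took the place of genes.

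Because C and G could not be told apart, the GATC target of the Dam methylase was studied within the S-A-T-S pattern, which also holds CATG, CATC and GATG. EcoKI targets were studied within the 3-letter form of their recognition sequence, and targets of the methylase YhdJ (ATGCAT) within A-T-S-S-A-T, leaving out places that overlap an S-A-T-S. A pair means the facing adenines on both strands of such a place. A pair was counted as methylated when both adenines had a level of at least 50% and a coverage of at least 10 in every library of the strain. For the level of methylated pairs over the whole chromosome, the pairs for each K12 library were chosen from the other K12 libraries. No library chose its own pairs there. Levels by gene, feature class, distance from the origin and dense window used the pairs methylated in all 3 K12 libraries. In those levels, and in the median level of single pairs, the K12 libraries chose their own pairs. Pairs for SCS110 were those chosen in K12. All other adenines are called outside the patterns. Contexts were formed from the 3 letters A, T and S, which gives 9 contexts with 1 base on each side and 81 with 2.

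The level of a class was the sum of unconverted bases divided by the sum of all bases over its adenines, for each library, and is given as the mean ± SD over 3 libraries. Strains were compared with exact two-sided permutation tests on the library values. With 3 against 3 libraries the smallest possible p is 0.1, and with 3 pairs in a sign-flip test it is 0.25. Single adenines covered by at least 10 bases in all 6 E. coli libraries were compared by a quasi-binomial logistic model with 0.5 added to both counts, a dispersion moderated across adenines and not below 1, and an F test with Benjamini-Hochberg adjustment. An adenine was called at an adjusted p below 0.05 and a difference of at least 30 points. This test was tested on simulated data for K12 against SCS110, with counts drawn for 200000 of the real adenines. It called 61 of 66 simulated differences of 80 points (92.4%), 30 of 67 of 40 points (44.8%) and 1 of 67 of 20 points (1.49%). The last size is below the 30-point minimum, and 10.4% of it passed the adjusted p. The test called 0 adenines without a difference. All other simulated adenines had equal levels in both strains, whereas in the data 41.8% of tested adenines had an unadjusted F-test p below 0.05. These shares therefore hold for the simulated setting only. Adenines outside the patterns were called within a strain by one-sided binomial tests against the level outside the patterns in the same library, with Benjamini-Hochberg adjustment and a level of at least 50% in all 3 libraries. The same rule with a level of at least 10% was used for mitochondrial adenines against the pooled mitochondrial level, and was repeated on SCS110 for comparison. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for an alternative test.

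The tests, their thresholds, the fixed gene list and the alternatives were chosen before the data were examined, except the classes written with S, the rule for partly methylated pairs, the inverted repeats, the comparison by adenine density, the tests of technical explanations and the alternatives named as chosen later. The slope test and the coverage test of mitochondrial adenines, and the repeats around S-A-T-S pairs and in mitochondrial DNA, were chosen after their own results were seen. The rule for named genes had 5 parts. It named a fixed list (flu, mtlA, carA, srlA, ppiA, dnaA, mioC, mnmG, seqA, dam, dcm, hsdM, hsdS, hsdR, mutH and yhdJ), GATC palindromes unmethylated in K12, the 10 called adenines outside the patterns with the highest level in each strain, the 10 called mitochondrial adenines with the highest level and the 10 with the largest excess over the SCS110 level of their context, and the mitochondrial genes with the highest and lowest levels. Ties in level were named in the order of their positions. The part on unmethylated GATC palindromes was not analysed here, because an unmethylated GATC and an S-A-T-S of another sequence look alike without the genome sequence. Partly methylated pairs were named in its place by a rule chosen after the data were seen. They had a coverage of at least 20 on both strands in each K12 library, a K12 level below 88%, an excess over adenines within 50 bp on the same strand of at least 15 points on average and 10 points in each library, an SCS110 level below 25% and a difference between strains of at least 20 points. Regions with dense pairs and genes without reads were also named after their values were seen, and the farthest complete bin from the origin and the SCS110 levels by feature class were added then.

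The E. coli libraries held 468734143 to 557356525 bases at adenines, with a median coverage of 173 to 210, and the mitochondrial libraries 122246021 to 224803110, with a median coverage of 8946.5 to 14551.5. Coverage at single adenines limits the precision of single levels, and Wilson intervals at 95% cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The labels do not say that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. The main tests did not pair libraries of the same replicate number. The alternatives changed the coverage minimum, the way levels were averaged, the thresholds, the test and the libraries used. Spike-in DNA named in the labels' protocols was not analysed here, and positions without any read were treated as not covered.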

Results

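The data map 6mA in the genomes of E. coli K12, of E. coli SCS110, a laboratory strain sold as lacking the Dam and Dcm methylases, and in mitochondrial DNA of the HepG2 liver cancer cell line. Each group held 3 libraries. At adenines, the K12 libraries held 557356525, 472377252 and 553195906 bases, and the SCS110 libraries 531870215, 503763911 and 468734143. Median coverage per adenine was 209, 173 and 210 in K12 and 196, 188 and 173 in SCS110. The HepG2 libraries held 122246021, 140701934 and 224803110 bases, with median coverages of 8946.5, 9468 and 14551.5. The E. coli tables listed 1142742 adenines on the plus strand and 1141382 on the minus strand, and for mitochondrial DNA there were 5124 on the plus and 4094 on the minus strand. All levels are shares of unconverted bases, computed from the deposited counts of converted and unconverted bases, and hold 6mA together with adenines left unconverted by the deaminase.

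The question behind the comparison of K12 with SCS110 was where adenine methylation lies in a genome with and without Dam, the methylase of GATC that marks DNA for mismatch repair and replication control. Methylated S-A-T-S pairs, the pattern that holds GATC, had a level of 97.9% ± 0.231 (SD, n = 3) in K12 and 8.11% ± 0.714 (SD, n = 3) in SCS110, a difference of 89.8 points. In K12, 19071 of 86319 covered S-A-T-S pairs were methylated on both strands. Among the 67248 other covered pairs, passes on 1 strand would coincide in 24.1 pairs if the strands were independent. That number leaves out the 19071 pairs, and an expectation for all covered pairs was not computed. Of the 19071 methylated pairs, 18945 lay above 90%, and the median pair stood at 98.3%. In SCS110, 52 of 84239 covered pairs passed the same rule, 49 of which were also among the K12 pairs. The difference in level was larger than the spread between libraries, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The methylated pairs were chosen by their K12 level, and over all S-A-T-S adenines without that choice the levels were 29.02% ± 0.991 (SD, n = 3) in K12 and 5.39% ± 0.587 (SD, n = 3) in SCS110 (exact permutation p = 0.1), a difference of 23.6 points that was 7.30 points when medians of single adenines were used. Of the 67248 covered S-A-T-S pairs not methylated on both strands, 3126, or 4.65%, passed the level threshold on only 1 strand in K12, against 4.94% of such EcoKI-pattern pairs and 7.80% of such A-T-S-S-A-T pairs. The S-A-T-S count was 5209 without K12 replicate 1, which loosens the rule, 1433 at a coverage of at least 30, 853 at a level threshold of 0.75 and 9423 at 0.25.

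EcoKI targets, the sites methylated by the HsdM and HsdS subunits of the type I restriction system, were methylated in both strains. Pairs of the EcoKI pattern that were methylated in K12 had a level of 97.1% ± 0.439 (SD, n = 3) in K12 and 95.7% ± 0.197 (SD, n = 3) in SCS110. Of the covered EcoKI-pattern pairs, 598 of 8476 were methylated on both strands in K12 and 588 of 8285 in SCS110, and 587 pairs were shared. Of the 11 pairs found in K12 alone, 10 were not covered in SCS110. The first adenine of AAC in the same pairs, a neighbour that EcoKI does not methylate, stood at 8.69% ± 1.19 (SD, n = 3) in K12 and 5.34% ± 0.488 (SD, n = 3) in SCS110. The strain difference of 1.37 points was larger than the spread between libraries, with an exact permutation p of 0.1, and 0.977 points when medians were used.

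The A-T-S-S-A-T pattern, which holds the ATGCAT target of the methylase YhdJ, had no methylated pair in either strain. Its target adenines stood at 9.63% ± 2.05 (SD, n = 3) in K12 and 4.22% ± 0.555 (SD, n = 3) in SCS110 (exact permutation p = 0.1). The first adenine of the same pattern, which YhdJ does not methylate, stood at 9.56% ± 2.12 (SD, n = 3) and 4.16% ± 0.490 (SD, n = 3). The counts of methylated pairs were 0 of 1205 in K12 and 0 of 1152 in SCS110. With a count of 0 taken to allow up to 3 pairs, the share could reach 0.249% in K12 and 0.260% in SCS110. These limits are for the pattern, which also holds sequences other than ATGCAT, and places overlapping an S-A-T-S were left out. They give no limit for ATGCAT itself. The difference of 5.41 points between strains was 9.83 points when single adenines were averaged with equal weight.

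**Figure D1:**
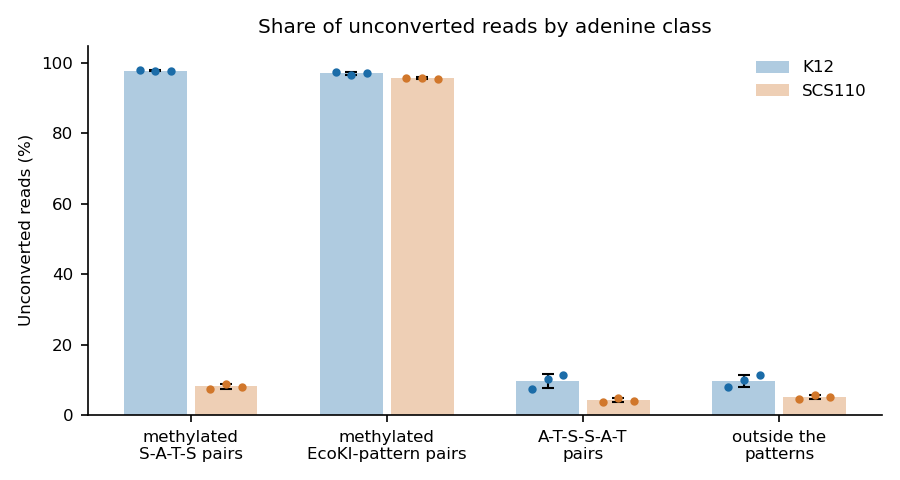
Share of unconverted bases in percent (vertical axis) by adenine class in K12 and SCS110; bars are means, points are the 3 libraries and error bars are SD. Methylated S-A-T-S pairs stood at 97.9% in K12 and 8.11% in SCS110, while EcoKI-pattern pairs stood at 97.1% and 95.7%.

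Adenines outside the patterns also had a higher share of unconverted bases in K12, at 9.76% ± 1.66 (SD, n = 3), than in SCS110, at 5.15% ± 0.578 (SD, n = 3), a ratio of 1.90 (exact permutation p = 0.1). All 9 contexts of 1 base on each side had the higher level in K12, each with an exact permutation p of 0.1, also after adjustment over the 9 contexts. TaS, an adenine after T and before C or G, had the lowest level, at 6.54% ± 1.38 in K12 and 2.64% ± 0.297 in SCS110 (SD, n = 3). The middle adenine of AaA had the highest, at 13.7% ± 2.52 and 7.60% ± 0.883 (SD, n = 3). The plus strand stood at 13.1% ± 2.31 in K12 and 6.57% ± 0.782 in SCS110 (SD, n = 3), and the minus strand at 6.51% ± 1.15 and 3.78% ± 0.382 (SD, n = 3). The strain difference of 4.62 points was 8.13 points when single adenines were averaged with equal weight.

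Levels outside the patterns followed the adenine density of the strand. The density was the number of adenines within 50 bp on each side, the adenine itself included, and levels and coverages were averaged over both strands. Where the strand held fewer than 15 adenines in this window, the level was 5.44% ± 0.516 in K12 and 3.29% ± 0.417 in SCS110 (SD, n = 3), at median coverages of 391 and 356. Where it held at least 40, the level was 45.6% ± 9.98 in K12 and 13.99% ± 5.18 in SCS110 (SD, n = 3), at median coverages of 29.5 and 37.3. The median number of unconverted bases changed far less, from 19 to 18.3 in K12 and from 8.33 to 6 in SCS110.

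**Figure D2:**
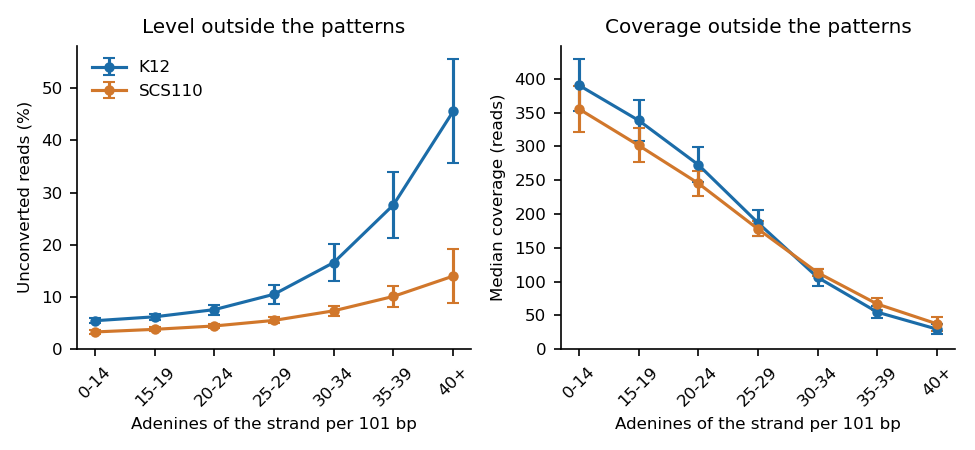
Level in percent and median coverage in bases (vertical axes) of adenines outside the patterns against the number of adenines on the same strand within 50 bp on each side (horizontal axes); points are means over 3 libraries and error bars are SD. The level was 5.44% in the sparsest and 45.6% in the densest K12 group, and coverage was 391 and 29.5.

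Single adenines were then compared between the strains. Among 2191921 adenines tested with the quasi-binomial model and Benjamini-Hochberg adjustment, 130650 were higher and 137 lower in K12. Methylated S-A-T-S pairs made up 37238 of the higher adenines, which was 99.4% of the 37472 tested in that class. The class was chosen by its level in the same K12 libraries, so a high share was partly built in. Of the other S-A-T-S adenines, 3584 of 132484, or 2.71%, were higher in K12. Among the methylated EcoKI-pattern adenines, 2 of 1178 were higher in K12, and of the A-T-S-S-A-T targets 132 of 2356. Outside the patterns 89332 of 2002892 adenines, or 4.46%, were higher and 132 were lower. The number of higher adenines was 82190 without K12 replicate 3, 72265 at a coverage of at least 30, 50246 with a difference of at least 0.5, 602998 with no minimum difference and 86470 with limma, and the number lower was 229 without SCS110 replicate 1 and 247 without SCS110 replicate 2. Outside the patterns the higher adenines numbered 55241 without K12 replicate 2, 42973 without K12 replicate 3 and 34857 at a coverage of at least 30.

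All genes of the fixed list held methylated S-A-T-S pairs in K12. Pairs were counted in each gene and the intergenic sequence on both of its sides, and gene coordinates are those of the E. coli chromosome, ASM584v2. Neighbouring genes therefore share pairs, and those between mnmG and mioC were counted for both genes. In the origin region, mioC (3926012 to 3926455), beside the replication origin, had 22 methylated pairs among 22 S-A-T-S pairs, at 98.3% ± 0.149 in K12 and 11.5% ± 1.71 in SCS110 (SD, n = 3). mnmG (3923744 to 3925633), a tRNA modification gene on the other side of the origin, had 35 of 62 at 97.9% ± 0.281 in K12 (SD, n = 3), and dnaA (3882326 to 3883729), which encodes the replication initiator, had 21 of 35 at 97.6% ± 0.11 (SD, n = 3). seqA (712987 to 713532), whose product binds hemimethylated GATC, had 2 of 14. The densest stretch of methylated pairs on the chromosome, named after its values were seen, lay between mnmG and mioC at 3925724 to 3925962, with 12 pairs in a window of 250 bp against a median of 2. Its level was 98.0% in K12 and 15.6% in SCS110. Windows with 10 pairs lay in recB (2955000 to 2955246), a subunit of the RecBCD nuclease, rpoN (3345260 to 3345507), the nitrogen sigma factor, and aaeR (3390126 to 3390373), a transcription regulator.

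Among the genes of methylation and its use, dam (3515077 to 3515913) had 5 methylated pairs at 98.1% ± 0.398 in K12 (SD, n = 3), hsdR (4583249 to 4586761), the restriction subunit of EcoKI, had 22 at 98.1% ± 0.225 (SD, n = 3), and yhdJ (3411653 to 3412537) had 10 at 98.4% ± 0.0801 (SD, n = 3). mutH (2969662 to 2970351), the mismatch repair nuclease that cuts unmethylated GATC, hsdM (4581459 to 4583048) and hsdS (4580068 to 4581462) had 4, 4 and 3 methylated pairs, at 98.5%, 98.3% and 98.2% in K12. dcm (2030899 to 2032317), the cytosine methylase gene, had 7 methylated pairs at 95.6% ± 1.26 (SD, n = 3). The genes dam and dcm were covered by reads in all SCS110 libraries.

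Some listed genes are known for regions kept from Dam by bound proteins. Of these, mtlA (3772281 to 3774194), the mannitol transporter, had 11 methylated pairs among 63 S-A-T-S pairs, at 98.0% ± 0.0316 in K12. carA (29651 to 30799), of carbamoyl phosphate synthesis, had 4 among 26 at 98.3% ± 0.0804. ppiA (3491725 to 3492297), a periplasmic prolyl isomerase, had 3 among 14 at 99.4% ± 0.148 (SD, n = 3 each). srlA (2825832 to 2826395), of sorbitol transport, had 2 methylated pairs among 11, at 89.2% ± 1.54 in K12 and 15.9% ± 3.49 in SCS110 (SD, n = 3). flu (2071539 to 2074658), the gene of the phase-variable antigen 43, had 1 methylated pair among 52, at 98.3% ± 0.795 (SD, n = 3). Pairs below the threshold in these genes could be GATC or another S-A-T-S sequence. The levels above hold only pairs that passed the threshold, so a GATC kept from Dam would not enter them. They therefore do not tell whether such regions were methylated. Directly before flu, 3 pairs in the small RNA gene isrC (2071317 to 2071511), named after their values were seen, stood at intermediate levels in K12. The pairs at 2071318, 2071337 and 2071350 had 75.1% ± 9.71, 79.0% ± 6.60 and 79.8% ± 7.44 in K12 and 8.16%, 19.04% and 23.5% in SCS110 (SD, n = 3). Adenines around the first of these pairs stood at 30.6% on the plus and 32.6% on the minus strand, and coverage there was 29 to 83 in K12.

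**Figure D3:**
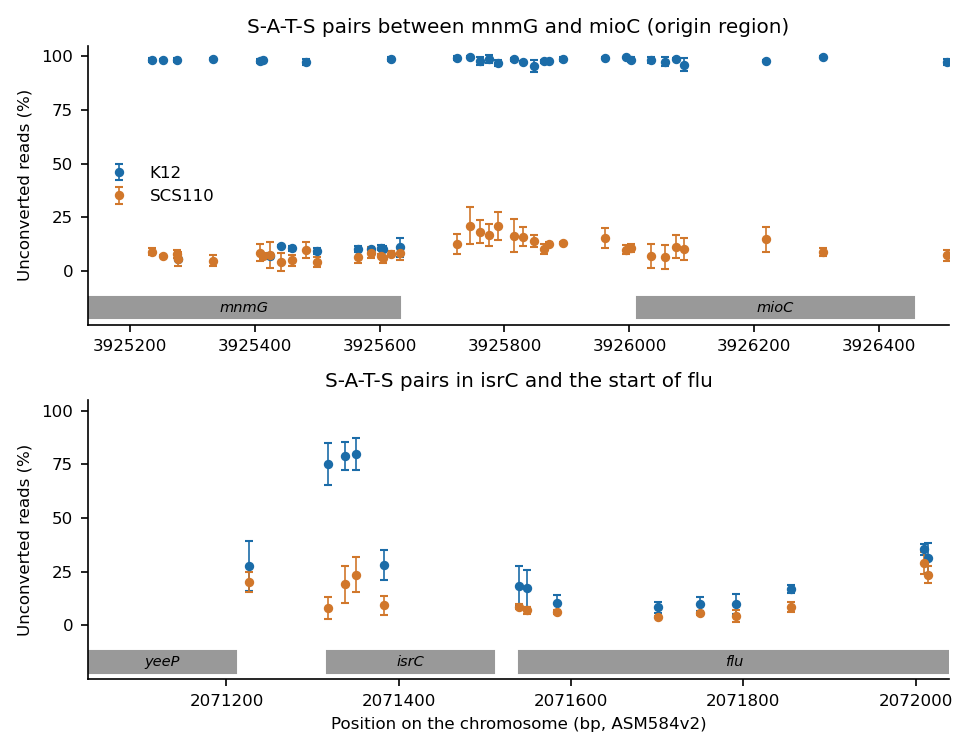
Levels in percent (vertical axes) of single S-A-T-S pairs by chromosome position in bp (horizontal axes) around the replication origin (upper panel) and in isrC and the start of flu (lower panel); points are means over 3 libraries, error bars are SD and grey boxes are genes. The 12 densest pairs between mnmG and mioC had a mean of 98.0% in K12, and 3 isrC pairs lay between 75.1% and 79.8%.

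By the rule for partly methylated pairs, 12 S-A-T-S pairs stood out in K12, 2 of them in isrC. Between comR and bhsA, the pair at 1169023 had the same level on both strands, 60.8% ± 3.21 on the plus and 60.8% ± 3.99 on the minus strand (SD, n = 3), and 6.07% ± 4.30 in SCS110. comR encodes a repressor and bhsA an outer membrane stress protein, and coverage at the pair was 27 to 73. Between fepD, of enterobactin uptake, and entS, of enterobactin export, the pair at 622228 had 33.3% ± 5.85 and 32.9% ± 4.63 on the plus and minus strands in K12 and 2.14% ± 2.81 in SCS110 (SD, n = 3), at a K12 coverage of 150 to 257. Neighbouring adenines there stood at 14.2% and 7.48%. In dacA (662752 to 663963), a penicillin-binding protein gene, the pair at 663332 had 97.3% ± 0.418 on the plus but 47.1% ± 1.92 on the minus strand (SD, n = 3), and in rcsD (2313488 to 2316160), of the Rcs phosphorelay, the pair at 2313566 had 97.1% ± 1.31 and 61.6% ± 10.1 (SD, n = 3). Minus-strand neighbours stood at 22.0% in dacA and 32.9% in rcsD, and the lowest coverage at these pairs was 35 and 22. The other pairs within genes lay in intF at 295783, aroL at 406426 and rpsM at 3442125. Those between genes lay between ddpX and dosP at 1563189, leuE and dmlR at 1880784, and yjhU and yjhF at 4520576. The K12 levels of all these other pairs, as means over both strands, were 82.3% to 87.6%. Each was higher on the plus strand, at 92.7% to 98.6%, than on the minus strand, at 66.1% to 77.7%, the same direction as in dacA and rcsD. The test between strains was run on single adenines and not on pairs, and its results for these adenines are not given here. The pairs were chosen by their levels in both strains.

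By feature class, 17485 of the methylated pairs lay in protein-coding genes, a density of 4.42 per kb, 532 in RNA genes and pseudogenes (2.81 per kb) and 1054 between genes (2.12 per kb). The K12 level was 97.9% ± 0.204 in protein-coding genes and 96.6% ± 0.301 between genes (SD, n = 3), and the intergenic level differed by -1.38 points ± 0.120 with an exact sign-flip p of 0.25, the smallest possible. In SCS110 the same pairs stood at 7.96% ± 0.700 in protein-coding genes and 12.2% ± 1.52 between genes (SD, n = 3), the opposite direction, by 4.22 points ± 1.08 (exact sign-flip p = 0.25). Coverage of the 100 kb bins next to the origin was 1.33 ± 0.0188 times that of the farthest bins in K12 and 1.25 ± 0.0459 times in SCS110 (SD, n = 3). The difference of this ratio between the strains had an exact permutation p of 0.1, and the excess at the origin itself was not tested. The level of methylated pairs in the same K12 bins was 97.9% ± 0.216 and 98.0% ± 0.149 (SD, n = 3), but the farthest bin was cut short and held 148 pairs. In the farthest complete bin, with 741 pairs, the level was lower than at the origin in 3 of 3 K12 libraries, by a change of -0.315 points ± 0.0725 (SD, n = 3, exact sign-flip p = 0.25), and the coverage ratio was 1.38 ± 0.0279 in K12 and 1.26 ± 0.0530 in SCS110 (SD, n = 3), with an exact permutation p of 0.1 for K12 against SCS110.

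Within each strain, adenines outside the patterns with a level of at least 50% in all 3 libraries were counted. K12 had 100483 of 2063774, or 4.87%, of which 77043 lay on the plus strand, and SCS110 had 13855 of 2012349, or 0.688%, of which 11268 lay on the plus strand. The strains shared 12241 of these adenines, against 513 expected if the strains were independent. That expectation takes every adenine as equally likely to be called. Levels depended on context, strand and adenine density in both strains, so some excess over it was built in. The highest level, 100% in every library, was shared by 359 adenines in K12 and 28 in SCS110. The 10 named for each strain are those with the lowest chromosome positions among these ties, and their lowest coverage was 10 to 27. In K12 they lay in caiC (36282, 36285 and 36291), a carnitine metabolism gene, between yabR and ilvI (85533), in arfB (215241), a ribosome rescue factor gene, and in yafT (237706 and 237707), ykfM (238666 and 238667) and yahO (346648), and SCS110 had 66.7% to 100% there. In SCS110 they lay in dnaQ (236744), the proofreading subunit of DNA polymerase III, yaiL (376881 and 376882), the protease gene lon (459604), tolA (776685, 776871 and 776872), of the Tol-Pal envelope system, tfaR (1432767) and fdnI (1551946 and 1551947), a formate dehydrogenase subunit, and K12 had 86.7% to 100% there. The K12 count was 160712 without K12 replicate 1, 40054 at a coverage of at least 30, 224578 at a level of at least 0.3 and 19671 at 0.8. The SCS110 count was 27554 without SCS110 replicate 1, 21403 without SCS110 replicate 3, 4946 at a coverage of at least 30, 40404 at a level of at least 0.3 and 1611 at 0.8. A call needs every library used to pass, so a higher count without 1 library was largely built in.

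The HepG2 libraries addressed how much 6mA human mitochondrial DNA holds, and positions are those of the mitochondrial genome in GRCh38.p13. The pooled level over all mitochondrial adenines was 2.35% ± 0.710 (SD, n = 3), against 5.15% of SCS110 adenines outside the patterns, and was weighted to the plus strand by its higher coverage. Adenines of the minus strand stood at 6.88% ± 3.80 and those of the plus strand at 1.76% ± 0.369 (SD, n = 3), against 3.78% on the minus and 6.57% on the plus strand outside the patterns in SCS110, and these differences from SCS110 were not tested. The minus strand was higher in 3 of 3 libraries, by 5.12 points ± 3.44 (SD, n = 3), with an exact sign-flip p of 0.25, the smallest possible for 3 libraries, and by 3.18 points without HepG2 replicate 3. Plus-strand coverage exceeded minus-strand coverage 9.68-fold ± 0.732 (SD, n = 3). With equal weight for each adenine the pooled level was 7.96% and the strand difference 10.2 points.

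Along the mitochondrial genome, positions 1001 to 3000, which hold most of the ribosomal RNA genes, had the reverse order of the strands. The plus strand stood at 5.87% ± 1.55 in positions 1001 to 2000 and 6.29% ± 1.11 in positions 2001 to 3000, and the minus strand at 2.69% ± 1.74 and 3.38% ± 2.15 (SD, n = 3). In these bins the minus strand had the higher coverage, with medians of 14295 to 19424 in positions 1001 to 2000 against 6215 to 11698 on the plus strand. In the other bins the minus strand stood at 5.38% to 13.6% and the plus strand at 1.17% to 2.22%.

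**Figure D4:**
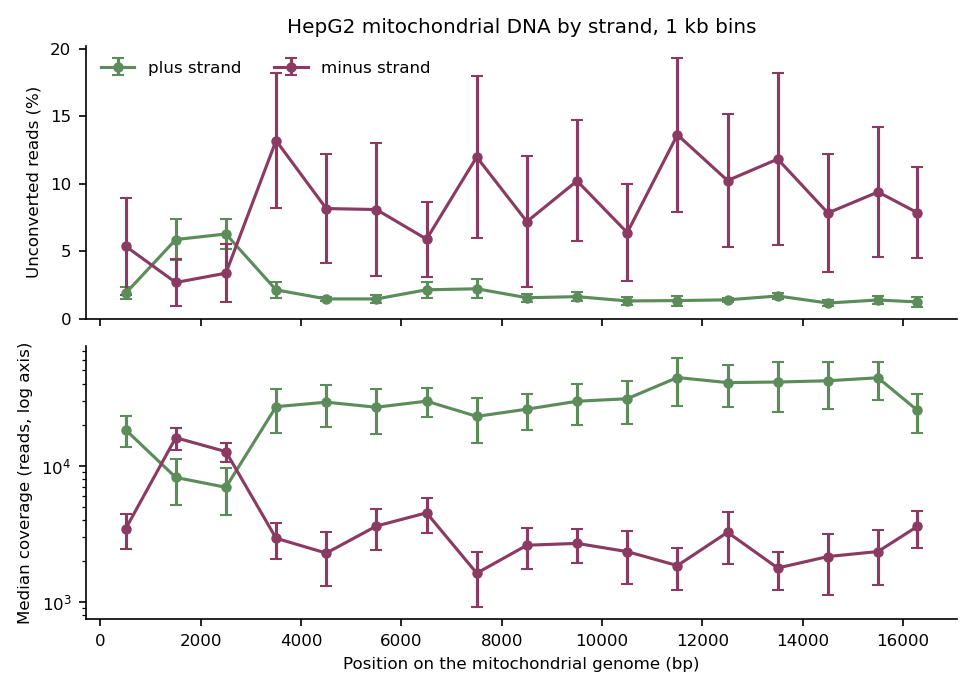
Level in percent (upper vertical axis) and median coverage in bases (lower vertical axis, log scale) of HepG2 mitochondrial adenines by strand in bins of 1000 bp along the genome (horizontal axis, bp); points are means over 3 libraries and error bars are SD. In positions 1001 to 3000 the plus strand had the higher level and the lower coverage.

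By the mitochondrial rule, 1427 of 9218 adenines, or 15.5%, were called, 1188 of them on the minus strand and 239 on the plus strand. The same rule called 150834 of 2012349 SCS110 adenines outside the patterns, or 7.50%. With a level of at least 0.3 the counts were 300 in HepG2 mitochondrial DNA, or 3.25%, and 40404 in SCS110, or 2.01%, and with a level of at least 0.5 they were 85, or 0.922%, and 13855, or 0.688%. At a level of at least 0.05 they were 2613, or 28.3%, and 159463, or 7.92%. By strand, the rule called 4.66% of plus-strand and 29.02% of minus-strand mitochondrial adenines, and 11.8% and 3.09% in SCS110. The mitochondrial count was 605 at a coverage of at least 1000. The 10 called adenines with the highest level all lay on the minus strand and were also the 10 with the largest excess over the SCS110 level of their context. The adenine at position 5446 had 89.2% ± 5.81 (SD, n = 3) at a coverage of 331 to 1321, against 5.83% for its context in SCS110 and a median of 31.9% among its neighbours. Position 7818 had 88.1% ± 6.64, position 3899 had 86.8% ± 4.19 at a coverage of 1377 to 2980, and position 3898 had 86.4% ± 4.23 (SD, n = 3). The median level around position 3899 was 12.6%. The other adenines, at positions 504, 10953, 5443, 6293, 12105 and 6241, had levels from 79.1% to 84.9%.

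Mitochondrial levels differed between sequence contexts. Across 81 contexts of 2 bases on each side, which are not independent replicates, the mitochondrial level and the SCS110 level had a Pearson r of 0.824 and a Spearman rho of 0.859. With 1 base on each side the values over 9 contexts were 0.943 and 0.933. No permutation p was attached to these correlations, since contexts are not samples.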

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

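The slope test and the coverage test of mitochondrial adenines below were chosen only after the result was seen, and the comparison with SCS110 was chosen before.

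The strands differed in opposite directions in E. coli and in mitochondrial DNA. In every K12 library the plus-strand level outside the patterns was above the minus-strand level, by 6.56 points on average (4.94 to 7.65), and in every SCS110 library by 2.79 points (2.54 to 3.28). In every HepG2 library the order was the reverse, with -5.12 points on average (-9.01 to -2.48). The results were singled out because all libraries of each E. coli strain lay on the other side of 0 from all HepG2 libraries, and the difference was not tested.

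In mitochondrial DNA the strand with the lower coverage had the higher level, also in positions 1001 to 3000, where the order of the strands was reversed. Loss of converted reads where coverage was low, methylation of the mitochondrial DNA, and incomplete deamination of the size seen in SCS110 cannot be told apart as its cause. The highest slope of unconverted on converted bases over windows of 100 bp, 0.154 on the log10 scale against 0.0145 to 0.373 in the E. coli libraries, and the 7.57% of called adenines with at least the median coverage of their strand both restate that levels were higher at low coverage, so neither decides between these explanations. SCS110 had 0.484 times the mitochondrial share of called adenines, and leaving out 1 library of each gave 0.522 to 0.816. A call needs every library used to pass, so leaving out 1 loosened the rule on both sides. The ratio also measures the power of the calls, which were made at median coverages of 173 to 196 in SCS110 and 8946.5 to 14551.5 in mitochondrial DNA. The SCS110 calls lay mostly on the plus strand, at 11.8% of adenines against 3.09% on the minus strand, while mitochondrial DNA had 4.66% and 29.02%.

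Of 4649 genes checked, 39 had no reads at over 90% of their adenines in every SCS110 library, against 0 genes in K12. They were singled out because the comparison of levels cannot use them while the K12 libraries covered them. They lay in 7 blocks of 46633 bp in total. The longest block ran from yghQ to yqhI (3131341 to 3147740) and held the hyb genes of hydrogenase 2 and gss, a glutathionylspermidine gene. Other blocks ran from ymfD to beeE (1196867 to 1206204) and from pinE to mcrA (1209685 to 1211179) in the e14 prophage, where mcrA encodes a restriction enzyme of modified cytosine. The remaining blocks were yagB to yagH (280385 to 288399), intZ to yffR (2558858 to 2564372), gatD to gatY (2171833 to 2177204), which holds galactitol genes, and rrrD (577613 to 578110).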

How the results depend on the processing

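Use of bases with the top quality letter alone and the mitochondrial coverage minimum of 1000 were chosen after seeing the data, and all other alternatives before. No result changed direction under any alternative run. Of the main results, 129 values under alternatives chosen before moved by less than the spread between libraries, or counts by less than 1.5 times, as did 12 under those chosen after, while 42 and 3 moved further. Of 136 values of named pairs and adenines under alternatives, 124 stayed within the spread and 12 moved. Of the 136, 114 left out 1 library, which cannot move a mean of 3 libraries by its SD, so these had to stay. With the top quality letter alone, 10 stayed and 12 moved, all 12 lower. The same limit applies to levels among the main results when 1 library is left out. Unless the setting itself changes what is counted, the cause was not tested. With the mean of single adenines, the strain difference in points was 87.0 for methylated S-A-T-S pairs, 9.83 for A-T-S-S-A-T and 8.13 outside the patterns, and in mitochondrial DNA the level was 7.96% and the strand difference 10.2. With medians, the strain difference was 91.1 for methylated S-A-T-S pairs, 7.30 for all S-A-T-S and 0.977 for EcoKI. With the top quality letter alone it was 90.4 for methylated and 20.7 for all S-A-T-S. Looser or stricter thresholds change what is counted: pairs with 1 methylated strand numbered 9423 at 0.25 and 853 at 0.75, adenines called outside the patterns 224578 at 0.3 and 19671 at 0.8 in K12 and 40404 and 1611 in SCS110, and mitochondrial calls 2613, 300 and 85 at 0.05, 0.3 and 0.5. At a coverage of at least 30, which leaves fewer adenines, these were 1433 pairs with 1 methylated strand, 40054 calls in K12 and 4946 in SCS110, and the test between strains gave 72265 higher, 34857 higher outside the patterns and 58 lower. A coverage of at least 1000 left 605 mitochondrial calls. Without a minimum difference the test gave 602998 higher, 529604 higher outside the patterns and 4773 lower, with a difference of at least 0.5 it gave 50246, 12776 and 9, and limma gave 86470, 47093 and 55. Libraries of the same number in K12 and SCS110 deviated together little, with correlations over adenines of 0.0816, 0.0635 and 0.0136, and K12 replicate 3 correlated better with SCS110 replicate 2 (0.0171) than with its own number. With a replicate block, which pairs these libraries, 132566 were higher and 142 lower, and 129187 of the 132708 called were also called without pairing. The mitochondrial and SCS110 contexts had an r of 0.943 with 1 base on each side. Leaving out each library in turn gave 3425 to 5209 pairs with 1 methylated strand (highest without K12 replicate 1), 82190 to 170560 higher adenines (lowest without K12 replicate 3), 118 to 247 lower (highest without SCS110 replicate 2, and 229 without replicate 1), 42973 to 127257 higher outside the patterns (lowest without K12 replicate 3, and 55241 without replicate 2), 109432 to 160712 calls in K12 (highest without replicate 1), and 19526 to 27554 in SCS110 (highest without replicate 1, and 21403 without replicate 3). Pairs with 1 methylated strand and calls within a strain need every library used to pass. Leaving 1 out loosens that rule, so a rise of these counts was largely built in. Alternatives for GATC palindromes unmethylated in K12 and for mitochondrial genes were not run, since no genome sequence or mitochondrial annotation was used. Depth limits single adenines most where the strand is rich in adenine, at a median coverage of 29.5 in K12.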

Other observations

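The tests of inverted repeats and of depth in SCS110, of the distance to methylated pairs, of batches and of other splits were chosen before their results were seen, and the repeats around S-A-T-S pairs and in mitochondrial DNA were looked for afterwards.

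In SCS110, the 52 S-A-T-S pairs that stayed unconverted on both strands lay mostly in inverted repeats and between genes. Of these pairs, 42 lay in stems of at least 8 bp, 33 in stems of at least 10 bp, and 38 between genes. Of all S-A-T-S pairs, 4.44% lay in stems of at least 8 bp, 0.969% in stems of at least 10 bp, and 8.12% between genes. All stems here and below were searched in the letters A, T and S, with S facing S counted as paired. A stem can therefore hold C facing C or G facing G, which do not pair. Loops held 3 to 8 bases in E. coli and up to 15 in mitochondrial DNA.

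The mitochondrial DNA of HepG2 held 70 of 9218 adenines that exceeded their neighbours by at least 30 points in all 3 libraries, or 0.759%, against 6561 of 2012349 in SCS110, or 0.326%. Of the 70, 19 lay in stems of at least 8 bp, or 27.1%, against 3.54% of all mitochondrial adenines. They came from only 4 places, with 8 adenines at 2102 to 2119, 6 at 5731 to 5762, 4 at 3898 to 3912 and 1 at 10953, and adenines of the same place are not independent, so no p is given. The 10 named mitochondrial adenines with the highest levels were all among the 70, and 7 of these 10 lay outside stems.

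The first pattern was the 13855 adenines outside the patterns that stayed unconverted in all SCS110 libraries. Of these, 8.73% lay in stems of at least 10 bp against 0.650% of all adenines, a ratio of 13.4, and stem adenines had a median of 6.71% against 4.68% in loops for stems of 10 to 11 bp and of 11.6% against 5.00% for stems of at least 12 bp, consistent, for the part in stems, with refolding that keeps the deaminase out. Among the 930 called adenines with at least the median coverage, 20.6% lay in stems. Low depth cannot be told apart as a cause for the rest, since 6.71% of the called adenines reached the median coverage of all adenines, but a level of at least 50% goes with low coverage wherever unconverted counts vary little. No biological explanation was tested.

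The other pattern was the higher level outside the patterns in K12 than in SCS110. A spread of the signal from methylated S-A-T-S pairs as the source of the whole excess was argued against. The excess of K12 was 5.53 points further than 200 bp from such pairs and 3.80 points within 20 bp, a ratio of 1.45. A smaller effect near the pairs stays open, since distances were not matched for adenine density. Levels in K12 and SCS110 were 5.44% and 3.29% at the lowest density and 45.6% and 13.99% at the highest. Loss of converted reads, named above for mitochondrial DNA, was not tested as a source of the K12 excess and stays open. A difference in library preparation cannot be told apart from the strain, as the labels gave 0 batches within the 6 libraries. The strain itself stays open as an untested biological explanation.

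The number of adenines called between the strains was 130787 in the real split of the 6 libraries, and the highest number in the other splits was 0. Every other split put libraries of both strains on each side. The strain difference then entered the dispersion, so a low count was built in and says little about chance. The real split alone, 1 of 10, gave as many, and 10 splits are too few for a share under 0.05. Those splits were run with the quasi-binomial model and Benjamini-Hochberg adjustment.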
